A study of Mus musculus with 4 samples.

How the data were processed

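Gene expression was measured by RNA sequencing in 4 lung samples of mice, 2 labelled Kras and 2 labelled Kras_prtn3, and groups were taken from the sample titles. RNA was extracted with Trizol and sequenced on the DNBSEQ platform, per the labels' protocols. The submitters' processing notes name HISAT2 (version 2.0.4), Bowtie2 (version 2.2.5), RSEM and the genome build mm10, without saying in which order or role they were used. Filters, the gene annotation and the use of strand are not given in the sources used here. The deposited table holds expected counts per gene, 1 column per sample, without scaling between samples. This unit was read from the values, of which 32.0% on average were not whole and whose columns totalled 19200987 to 19585427. An expected count splits a read that matches several genes among them, so values of genes with near-identical copies are estimates.

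The table lists 17874 rows by gene symbol. One symbol, Plin2, names a second row, which was kept apart and is not reported. A RefSeq table of assembly GRCm38.p6, the assembly that mm10 names, gave chromosomes and 1-based positions. It matched 17416 rows by symbol and 284 by synonym, and 174 were unmatched. Of the matched rows, 99.0% were protein-coding genes. No mitochondrially encoded gene under the symbols searched was listed, so mitochondrial RNA could not be used to judge sample quality.

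Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 14531, and libraries were scaled by TMM (factors 0.956 to 1.025). The groups were compared with edgeR's quasi-likelihood F test (edgeR version 4.0.16, R version 4.3.3, trended dispersion, default settings) on all 4 samples with no covariate. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjustment over a list alone used the edgeR p-values of its members. Log2 fold changes are Kras_prtn3 over Kras and are given with a standard error derived from the F statistic, and CPM values are TMM-scaled and given as mean ± SD of 2 libraries. For genes under the filter, the ratio of summed counts has an exact 95% interval from the binomial distribution conditional on the total, and a count of 0 was taken to allow up to 3 counts. These intervals cover counting error only.

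Gene lists of cell type markers, pathways and sample make-up (37 lists, 618 distinct genes) were fixed before the data were examined, as were the comparison, the alternatives and the rule for named genes. Of the lists, 34 had at least 3 tested members and were tested with camera (limma version 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the 34. The azurophil granule, airway basal cell and mitochondrial lists had too few. No list passed when the correlation was estimated from the data, in a design with few residual degrees of freedom (smallest adjusted p 0.246), or in the directional fry test (smallest adjusted p 0.194). The mixed fry test, which counts changes in either direction and does not compare members with other genes, called 11 lists. Named genes were a fixed set around Prtn3, CXCL9, interferon-gamma and cytotoxic cells. To these were added the 10 called genes with the largest fold change in each direction with a mean of at least 1 CPM and no overlap between groups, passing over predicted genes. From each described list up to 4 called members were taken, or, with none, up to 3 of the most abundant. Ctsg and Cxcl11 of the fixed set were not listed.

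Replicates within a group differed by more than counting error. The chi-square per gene was 11.1 on average for the Kras pair and 13.6 for the Kras_prtn3 pair, against 24.1 to 31.8 for pairs across groups, so no library was counted as a copy of another. The procedure was tested on simulated data drawn from these means, library sizes and dispersions (10 simulations, 14531 genes, 200 changed). It recovered 75.0% of genes changed by 1 on the log2 scale and 95.9% of those changed by 2. On average 12.0% of the calls were false, above the nominal 5%. With no gene changed, 4.6 genes were called on average and 8 at most. A list shifted by a known amount was recovered in 10 of 10 simulations. Genes were drawn independently there, so this does not test set calls at the correlations estimated in these data. These differed by list, such as 0.82 for interferon-gamma response and -0.03 for club and goblet markers.

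The alternatives were DESeq2 (version 1.42.0), limma-voom, other scalings, other low-count filters, a robust fit, a fit with the replicate number as a block, stricter thresholds and leaving out each library. DESeq2 gave an adjusted p for 13000 genes, and a gene without one was counted as not called. The legacy form of the quasi-likelihood fit, meant as a variation, proved to be the default, and the newer form was run in its place. The newer form and a fit on autosomal genes only were chosen after seeing the data.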

Results

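RNA sequencing was carried out on lung samples of mice labelled Kras and Kras_prtn3. The study's design text speaks of lung tumours of K and KP mice and does not say which label each abbreviation stands for. Kras encodes a small GTPase whose activating mutations drive lung adenocarcinoma. Prtn3 encodes proteinase 3, a serine protease stored in the azurophil granules of neutrophils. The study's title names proteolytic cleavage of the chemokine CXCL9 by PRTN3 and its effect on cytotoxic immune cells as the subject. The labels do not say how Prtn3 was altered in the Kras_prtn3 mice. Each group held 2 samples, numbered 1 and 2. Polyadenylated RNA was sequenced on the DNBSEQ platform, which reads amplified DNA nanoballs. The 4 libraries held between 19200987 and 19585427 estimated counts, spread over 16704 to 16868 genes with a value above 0. Sftpc, the surfactant protein C gene of alveolar type 2 cells, took between 8.53% and 9.56% of each library. Nothing in the labels states that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

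The gene named in the Kras_prtn3 label was near the detection limit in every library. Prtn3 (GRCm38 chromosome 10, 79879667 to 79883174) had 7 and 3 counts in the Kras libraries and 2 and 6 in the Kras_prtn3 libraries. The Kras_prtn3 to Kras ratio of its depth-scaled counts was 0.769 (exact 95% interval 0.264 to 2.17, counting error only), so a difference was not detectable at this depth. Its neighbour Elane (neutrophil elastase; chromosome 10, 79886312 to 79888216) had 2 and 3 counts in the Kras libraries and 0 in both Kras_prtn3 libraries, where a count of 0 allows up to 3. Mpo, which encodes myeloperoxidase of the same granules, had 7 and 10 counts against 0 and 1, a ratio of 0.0566 (exact 95% interval 0.00135 to 0.361). Prss57, another granule protease, had 18 counts in each group. Elastase, myeloperoxidase and Prss57 belong to a list of 6 measured azurophil granule genes, none of which passed the low-count filter. When all genes were tested without that filter, the adjusted p was 0.852 for Prtn3, 0.313 for Elane and 0.166 for Mpo (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Kras itself was at 56.4 ± 3.26 CPM (counts scaled to library size; SD, n = 2) in the Kras group and 63.4 ± 0.421 in the Kras_prtn3 group, with an adjusted p of 0.364 in edgeR. Trp53, the p53 tumour suppressor gene, was at 71.5 ± 9.96 and 70.4 ± 9.37 CPM, with an adjusted p of 0.948 in edgeR.

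The groups also differed in genes of the Y chromosome. Ddx3y had 379 and 300 counts in the Kras libraries and 1 in each Kras_prtn3 library, and Kdm5d had 254 and 173 against 2 and 2. Uty and Eif2s3y, which have close X-linked relatives that can share reads, had Kras_prtn3 to Kras ratios of 0.109 (exact 95% interval 0.0743 to 0.154) and 0.0461 (0.0317 to 0.0651). These 4 Y-linked genes, the tested members of the sex-linked list, all fell, with adjusted p between 0.000132 for Ddx3y and 0.00774 for Eif2s3y (edgeR). No Y-linked gene outside the list was called. The 4-gene list was lower by camera (adjusted p = 3.51e-53) and not with an inter-gene correlation estimated from the 4 libraries (adjusted p = 0.246). The X-linked partners Ddx3x (log2 fold change 0.96 ± 0.11 SE), Eif2s3x (0.86 ± 0.10) and Kdm6a (0.96 ± 0.16), named after their values were seen, were higher in Kras_prtn3. Of 454 tested X-linked genes, 1.98% were called higher in Kras_prtn3, against 0.37% of the other genes (Fisher's exact test, two-sided p = 0.000107). The X-linked genes Awat1 (-2.51 ± 0.35) and Gprasp1 (-0.86 ± 0.13) were called lower. The median log2 fold change of all tested X-linked genes was 0.04. Every difference between the groups given here runs along this Y-linked difference, and the sex it marks and the group cannot be told apart.

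Between the groups, 117 of 14531 tested genes changed (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 61 were higher and 56 lower in Kras_prtn3, with a median absolute log2 fold change of 0.87. The largest increases were in Htr2c, a serotonin receptor gene (2.11 ± 0.33 on the log2 scale), Tlr8 (1.73 ± 0.15) and Mmp8, a collagenase gene (1.54 ± 0.17). They were followed by Tlr7 (1.53 ± 0.13), the clock gene Per1 (1.49 ± 0.20) and Ereg, an EGF receptor ligand gene (1.48 ± 0.18). Lilr4b (1.47 ± 0.10), Cybb (1.28 ± 0.10), Pira2 (1.28 ± 0.12) and Mrc1 (1.20 ± 0.12) completed the 10. Tlr7 and Tlr8 encode endosomal RNA sensors and lie close together on the X chromosome (Tlr8 at 167241123 to 167264329, Tlr7 at 167303380 to 167330574), and Cybb, the phagocyte NADPH oxidase subunit, is also X-linked. Tlr7 stood at 7.18 ± 0.121 CPM in Kras and 20.8 ± 1.5 in Kras_prtn3, and Cybb at 115.6 ± 2.55 and 281.3 ± 26.2 CPM (SD, n = 2). Lilr4b and Pira2 belong to receptor families with near-identical members, so their counts are uncertain. Apart from the Y-linked genes, the largest decreases were in Ngp, the neutrophilic granule protein gene (log2 fold change -4.42 ± 0.48), Awat1 (-2.51 ± 0.35), the heat shock gene Hsph1 (-1.95 ± 0.28) and Rorc (-1.90 ± 0.30). Rassf10 (-1.61 ± 0.19) and Derl3, a gene of endoplasmic reticulum protein disposal (-1.34 ± 0.16), followed. Adjusted p-values of these 20 genes lay between 0.000132 for Ddx3y and 0.0414 for Rorc (edgeR).

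**Figure D1:**
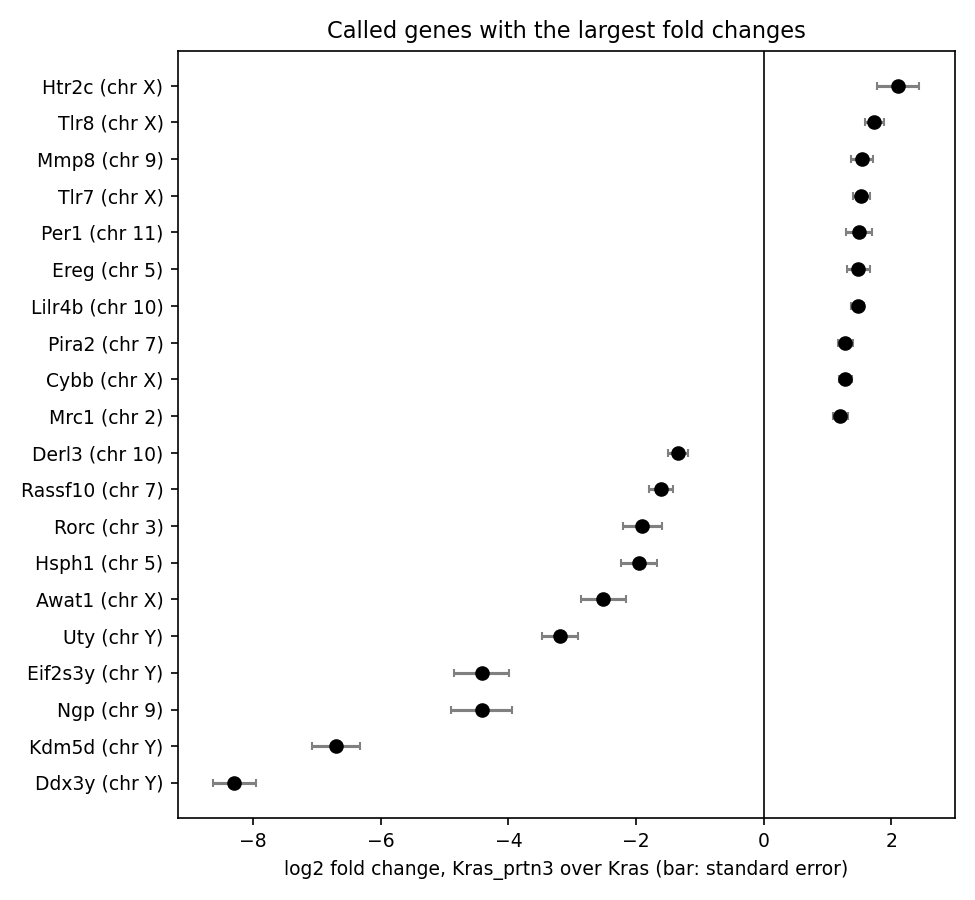
Log2 fold change (x axis, Kras_prtn3 over Kras, n = 2 per group) of the 20 called genes chosen by rule, with standard errors as bars and the chromosome beside each symbol. Values run from -8.29 for Ddx3y to 2.11 for Htr2c, and 4 of the 10 lowest lie on the Y chromosome.

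Leaving out a library leaves 1 sample in its group, whose spread is then taken from the other group. Passes of genes or lists in such fits, here and below, are therefore no evidence of a change. The count rested on few libraries. Without Kras replicate 1 it was 10 genes and without Kras replicate 2 it was 5, against 506 without Kras_prtn3 replicate 1 and 316 without Kras_prtn3 replicate 2; scaling by library totals alone gave 104 higher and 36 lower. Of 42 named genes that passed, Lilr4b, Ddx3y, Kdm5d and Eif2s3y alone still did without Kras replicate 1 and the last 3 of these without Kras replicate 2, and none changed sign in any of these fits.

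The study's question about CXCL9 and cytotoxic immune cells was looked at only through transcripts of the chemokine axis, T cell and cytotoxic genes. RNA levels do not measure cleavage of the CXCL9 protein, so they leave that question open. Cxcl9 (chromosome 5, 92321331 to 92328079), an interferon-gamma-induced chemokine gene, stood at 40.9 ± 3.90 CPM in Kras and 31.4 ± 7.42 CPM in Kras_prtn3 (SD, n = 2), a log2 difference of -0.38 ± 0.16 that did not pass the test (adjusted p = 0.234, edgeR). Without Kras_prtn3 replicate 1 it stood at -0.64 and passed (adjusted p = 0.036), without Kras_prtn3 replicate 2 it stood at -0.15, and over the alternatives its adjusted p ran from 0.0121 to 0.621. Cxcl10 (-0.26 ± 0.30) and the receptor gene Cxcr3 (-0.26 ± 0.27) did not pass either, and without Kras_prtn3 replicate 2 they stood at 0.18 and 0.05. The 3 tested genes of this axis gave an adjusted p of 0.22 as a set (camera), 0.758 with an estimated correlation, and 0.0039 without Kras_prtn3 replicate 1. None of the 15 tested cytotoxic effector genes changed over all genes in edgeR or limma-voom, or adjusted over the list alone in edgeR, and 4 had an unadjusted p under 0.05 in edgeR. DESeq2 called none either, but it gave an adjusted p for 13000 genes only, and low-count genes of this list may have had none. The largest changes among these 15, named after their values were seen, were in Gzmk (granzyme K, -1.16 ± 0.38, unadjusted p = 0.0172) and Prf1 (perforin, -1.05 ± 0.33, unadjusted p = 0.0139). Gzmb (granzyme B) was at 0.46 ± 0.35, Ccl5 at -0.45 ± 0.18, Il2rb at -0.38 ± 0.14 and Nkg7 at -0.53 ± 0.26 on the log2 scale, and the set had an adjusted p of 0.343 (camera), 0.674 with an estimated correlation. Without Kras replicate 1, Gzmb stood at 0.28 and Nkg7 at -0.20, without Kras_prtn3 replicate 2 at 0.27 and -0.23, and Nkg7 stood at -0.89 without Kras_prtn3 replicate 1. Ifng had 26 counts in the Kras group and 13 in Kras_prtn3, a ratio of 0.481 (exact 95% interval 0.227 to 0.97), and was under the filter (adjusted p = 0.371 without it, edgeR). Ccl5 passed without Kras_prtn3 replicate 1 (-0.76) and stood at -0.20 without Kras_prtn3 replicate 2. Of 18 T cell markers, 17 had a negative log2 fold change. None passed over all genes in edgeR, limma-voom or DESeq2, or adjusted over the list alone in edgeR, and 2 had an unadjusted p under 0.05 in edgeR. Examples are Cd4 at -0.60 ± 0.19, Cd8a at -0.05 ± 0.18 (0.00 with library totals only) and Cd2, the exception, at 0.47 ± 0.24. Cd2 stood at 0.20 and 0.81 without Kras replicate 1 and 2, and at 0.76 and 0.11 without Kras_prtn3 replicate 1 and 2. As a set they were lower (camera, adjusted p = 0.0379), but not with an estimated correlation (adjusted p = 0.674). That call was lost with DESeq2 (adjusted p = 0.0562), without Kras replicate 1 (adjusted p = 0.126) and without Kras_prtn3 replicate 2 (adjusted p = 0.168). Of the 16 checkpoint and regulatory T cell genes, 10 were above 0, Cd274 (0.25 ± 0.09) and Havcr2 (0.45 ± 0.11) among them, and 6 below. As a set they gave an adjusted p of 0.728 (camera), with a median of 0.07 and a mean that rounds to 0.00 from below. None of the 16 passed alone in the 3 tools. Their median was 0.16 without Kras replicate 1 and -0.04 without Kras replicate 2.

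Genes of antigen presentation and of the interferon-gamma response stood lower in Kras_prtn3 as sets. All 10 MHC class II genes had a negative log2 fold change (median -0.41, SD 0.40), of which H2-DMb2 fell on its own (-1.21 ± 0.16, adjusted p = 0.0248, edgeR) and 8 passed adjusted over the list alone. Cd74, the invariant chain gene, at -0.46 ± 0.10 (adjusted p = 0.0781), and H2-Aa, at -0.40 ± 0.09, were named after their values were seen. Of 17 MHC class I genes, 14 had a negative value (median -0.34, SD 0.28). H2-K1 (chromosome 17, 33996012 to 34000619) fell from 3300.0 ± 124 to 2166 ± 142 CPM (log2 fold change -0.61 ± 0.10, adjusted p = 0.0453, edgeR), and 12 passed adjusted over the list alone. H2-D1 (-0.49 ± 0.10) and B2m (-0.59 ± 0.12), named after the fact, did not pass over all genes in edgeR or limma-voom, and did in DESeq2 and in the robust edgeR fit. DESeq2 called 6 class II genes, Cd74 and H2-Aa among them, and 5 class I genes, and limma-voom called 1 of each. Members of the H2 family share reads, so their single values are uncertain. Of 22 interferon-gamma response genes, 21 were below 0 (median -0.44, SD 0.33), including Stat1 at -0.43 ± 0.09 and Gbp2 at -0.48 ± 0.12. None passed over all genes in edgeR, against 1 in limma-voom and 3 in DESeq2, and 9 passed adjusted over the list alone. Stat1 passed in DESeq2 and in the robust edgeR fit. Without Kras_prtn3 replicate 2 the list median was -0.27. Gbp2 and B2m passed without Kras_prtn3 replicate 1. By camera the adjusted p was 8.2e-08 for class II, 1.72e-07 for class I and 1.33e-08 for the interferon-gamma list. With an estimated correlation the adjusted p was 0.54 for both MHC lists and 0.674 for the interferon-gamma list. The 20 type I interferon response genes, Oasl2 (-0.10 ± 0.13) among them, had a median of -0.01, a mean of 0.01 and an adjusted p of 0.995 (camera, downward), so these differ in sign.

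Alveolar macrophage markers stood higher in Kras_prtn3. All 16 had a positive log2 fold change (median 0.67, SD 0.50), and 4 rose on their own in edgeR (5 in limma-voom, 6 in DESeq2). The 4 were Mrc1, the mannose receptor gene (62.9 ± 5.81 to 144.1 ± 16.4 CPM, adjusted p = 0.00774), Fabp4 (1.13 ± 0.12), the protease gene Ctsk (0.95 ± 0.10) and Atp6v0d2 (0.62 ± 0.09). Adjusted over the list alone, 11 rose. Chil3 (0.72 ± 0.18), Marco (1.85 ± 0.36), Ear1 (0.10 ± 0.22) and Ear2 (0.06 ± 0.10) were named after their values were seen. They did not pass over all genes in edgeR, although Marco did in limma-voom. When a library was left out, Marco ran from 1.31 to 2.72. Chil3 stood at 0.47 without Kras replicate 1. Ear1 and Ear2, which share reads, stood at -0.25 and -0.02 without Kras replicate 1. The set gave an adjusted p of 1.7e-17 (camera) and 0.54 with an estimated correlation. The 21 other monocyte and macrophage markers did not move as a set (median -0.14, adjusted p = 0.115, camera), although they were lower with DESeq2 (adjusted p = 0.0422), without Kras replicate 2 (adjusted p = 0.0116) and without Kras_prtn3 replicate 1 (adjusted p = 0.034). None passed over all genes in edgeR or limma-voom, 4 did in DESeq2, and 4 fell adjusted over the list alone. Cd68 was at 0.33 ± 0.13 (0.13 without Kras_prtn3 replicate 1 and 0.51 without replicate 2). The complement genes C1qa (-0.58 ± 0.15) and C1qc (-0.61 ± 0.15), named after the fact, lay below 0 and passed without Kras_prtn3 replicate 1. Mature neutrophil markers went both ways. Ngp fell from 45 and 63 counts to 2 and 3, Mmp8 rose from 5.45 ± 0.753 to 15.9 ± 1.89 CPM, and the other 14 tested markers did not pass over all genes in edgeR or limma-voom. Of these 14, Clec4e (1.47 ± 0.27, passing over all genes in the robust edgeR fit and without Kras_prtn3 replicate 1) rose and Mmp9 (-2.77 ± 0.59) and the calgranulin gene S100a9 (-1.62 ± 0.50) fell adjusted over the list alone, and S100a8 (-1.01 ± 0.51) did not pass. These 4 were named after the fact, and DESeq2 called Clec4e and Mmp9 over all genes. Ngp was not called by DESeq2, where its low counts may have left it without an adjusted p. Without Kras replicate 1, Mmp9 stood at -1.62, S100a9 at -0.62 and S100a8 at -0.25, and S100a8 stood at -0.46 without Kras_prtn3 replicate 1 and -1.9 without Kras_prtn3 replicate 2. The list had an adjusted p of 0.423 (camera). It was lower without Kras replicate 2 (adjusted p = 0.000216) and without Kras_prtn3 replicate 2 (adjusted p = 0.0232). The 15 dendritic cell markers (median -0.20) and the 6 tested mast cell, basophil and eosinophil markers (median -0.27, or -0.16 without Kras replicate 2, -0.12 without Kras_prtn3 replicate 1 and -0.59 without Kras_prtn3 replicate 2) were lower as sets, with adjusted p of 0.0314 and 0.0371 (camera), and without a called member in edgeR, where 3 and 2 members had an unadjusted p under 0.05 (DESeq2 called 0 and 1). With an estimated correlation the adjusted p was 0.54 and 0.674. Examples are Fscn1 (-0.16 ± 0.11) and Ccl22 (-0.29 ± 0.11) of the dendritic cell list and Hdc (-0.27 ± 0.24) and Kit (-0.26 ± 0.11) of the mast cell, basophil and eosinophil list. Of the latter list's 14 measured genes only 6 passed the low-count filter, and its transcripts were not assigned to cells. Fscn1 ran from -0.25 without Kras replicate 1 to -0.05 without Kras replicate 2. Without Kras_prtn3 replicate 1, Hdc stood at 0.10 and Kit at -0.14, and without Kras_prtn3 replicate 2 at -0.78 and -0.39. The dendritic cell call was lost with DESeq2 (adjusted p = 0.07), without Kras replicate 1 (adjusted p = 0.103) and without Kras_prtn3 replicate 1 (adjusted p = 0.092). The mast cell call was lost with DESeq2 (adjusted p = 0.0562), limma-voom (adjusted p = 0.0787) and no low-count filter (adjusted p = 0.126), without Kras replicate 2 (adjusted p = 0.284) and without Kras_prtn3 replicate 1 (adjusted p = 0.272). Adjusted over the list alone, no dendritic cell marker and 1 mast cell list member passed. Of 14 tested B and plasma cell markers, 6 were above 0 and 8 below, and they did not shift in one direction as a set (adjusted p = 0.728, camera). Jchain, the antibody joining chain gene, stood at -1.35 ± 0.41 (adjusted p = 0.139, edgeR). It stood at -2.36 without Kras_prtn3 replicate 1 and -0.76 without Kras_prtn3 replicate 2.

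**Figure D2:**
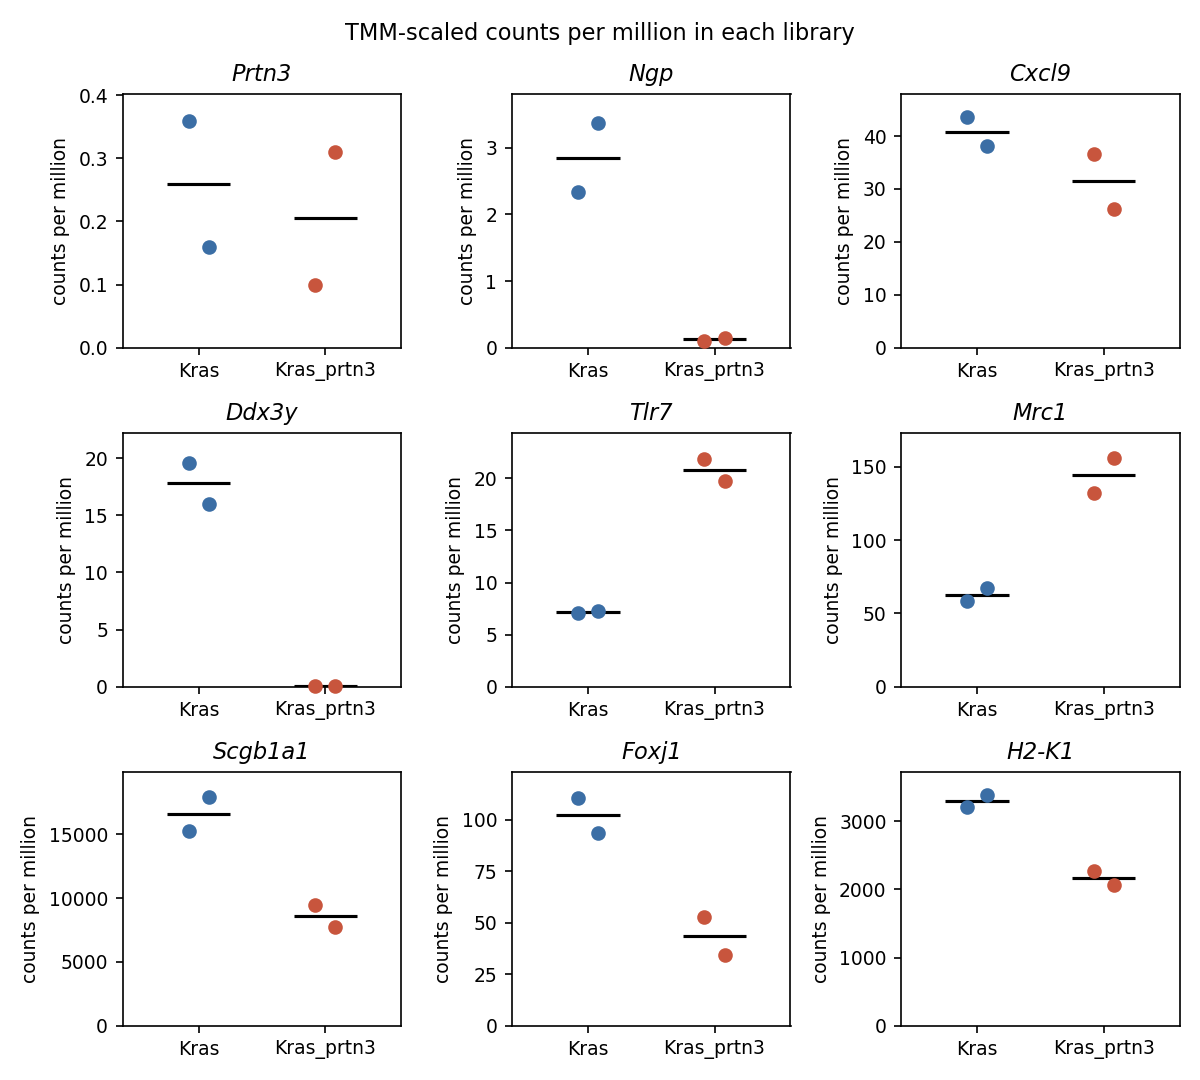
TMM-scaled CPM (y axis, from 0) of 9 genes in each library, as points, with group means as bars, n = 2 per group. Prtn3 overlaps between the groups, whereas Ddx3y, Ngp and H2-K1 lie lower and Tlr7 and Mrc1 higher in both Kras_prtn3 libraries than in both Kras libraries.

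Airway epithelial genes stood lower in Kras_prtn3. All 16 club and goblet cell markers had a negative log2 fold change (median -0.88, SD 0.73), and 5 fell in edgeR. The list mean of -1.09 was -0.49 without Kras replicate 1 and -2.59 without Kras_prtn3 replicate 1, as libraries within each group stood far apart in secretory genes such as Scgb3a1 (831.09 and 274.33 CPM in Kras, 362.57 and 9.0 in Kras_prtn3), named after its values were seen and passing without Kras_prtn3 replicate 1. Scgb1a1 (chromosome 19, 9083642 to 9087956), which encodes the main secretory protein of club cells, fell from 16606 ± 1881 to 8606 ± 1254 CPM (log2 fold change -0.95 ± 0.14, adjusted p = 0.0353). Scgb3a2 (-1.05 ± 0.16), Gabrp (-0.86 ± 0.11) and the cytochrome P450 gene Cyp2f2 (-0.80 ± 0.10) fell as well, and 9 markers passed adjusted over the list alone. All 19 tested ciliated cell markers were also below 0 (median -0.62, SD 0.25). Foxj1, the master transcription factor of motile cilia, fell from 102.2 ± 11.8 to 43.5 ± 13.1 CPM (adjusted p = 0.0399, edgeR), and 12 passed adjusted over the list alone. Without Kras replicate 1 the ciliated median was -0.41. The sets gave adjusted p of 1.13e-14 and 2.09e-11 (camera), and 0.246 and 0.54 with an estimated correlation. Markers of the alveolar epithelium did not pass as sets in the main test. The 17 alveolar type 2 markers had a median of -0.08 and an adjusted p of 0.198 (camera), or 0.0393 and lower with DESeq2, with Sftpc at -0.13 ± 0.13 (from -0.22 without Kras replicate 1 to -0.02 without Kras replicate 2) and Sftpb at -0.26 ± 0.11. The list median was -0.15 without Kras replicate 1 and also without Kras_prtn3 replicate 2. The 15 alveolar type 1 markers, with Ager at -0.06 ± 0.12, had a median of 0.05 and an adjusted p of 0.596 (camera). None of either list passed in edgeR, over all genes or adjusted over the list alone, while DESeq2 called 2 and 1.

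Transcripts of the next lists were not assigned to a cell type, so they cannot be tied to tumour cells. Among lists of growth, tumour progression and stress, 27 of 28 cell cycle genes had a positive log2 fold change (median 0.45, SD 0.24). None passed over all genes in edgeR, limma-voom or DESeq2, or adjusted over the list alone in edgeR, and 12 had an unadjusted p under 0.05. Pcna stood at 0.25 ± 0.10 (0.15 without Kras_prtn3 replicate 2), and Ccnb2 and Ccna2, named after the fact, stood at 0.91 ± 0.22 and 0.66 ± 0.16 and passed without Kras_prtn3 replicate 1. The set was higher (camera, adjusted p = 3.18e-06), but not with an estimated correlation (adjusted p = 0.674) or without Kras_prtn3 replicate 2 (adjusted p = 0.0691, mean 0.20), and its median was 0.69 without Kras_prtn3 replicate 1. Of 18 MAPK output genes, 2 rose (3 adjusted over the list alone), both EGF receptor ligand genes. These were Areg (22.2 ± 1.05 to 41.7 ± 3.65 CPM, adjusted p = 0.0139, edgeR) and Ereg (4.21 ± 0.354 to 11.8 ± 1.51 CPM). The list's median was 0.12 (0.01 without Kras replicate 2, -0.03 without Kras_prtn3 replicate 1 and over 1.5 times higher without either of the others, at 0.20 and 0.26) and its adjusted p 0.0185 (camera), or 0.742 with an estimated correlation. That call was lost with limma-voom (adjusted p = 0.0806) and no low-count filter (adjusted p = 0.0557), without Kras replicate 2 (adjusted p = 0.151) and without Kras_prtn3 replicate 1 (adjusted p = 0.309). Genes linked to lung adenocarcinoma progression did not shift in one direction as a set (adjusted p = 0.781, camera, median 0.08, mean -0.01). The mixed fry test, which counts changes in either direction, gave an adjusted p of 0.0168. Within this list the tight junction gene Cldn4 rose (1.18 ± 0.12, adjusted p = 0.0117) and the lung transcription factor gene Foxa1 fell (-0.61 ± 0.10, adjusted p = 0.0414, edgeR). Hypoxia and glycolysis genes gave an adjusted p of 0.519, immediate early and stress genes 0.0521, and inflammatory chemokine and cytokine genes 0.165 (camera). Without Kras replicate 2 and without Kras_prtn3 replicate 1 the stress list was higher (adjusted p = 0.00599 and 1.09e-07) and the chemokine list lower (6.31e-05 and 0.0454). The stress list was also higher with DESeq2 (0.00785), limma-voom (0.0314), no low-count filter (0.0326) and autosomal genes only (0.0453). In the stress list Hsph1 fell from 59.4 ± 16.8 to 15.4 ± 6.5 CPM, and adjusted over the list alone 4 rose and 1 fell.

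In the stroma, Eln (elastin) rose from 569.3 ± 54.3 to 1044.8 ± 43.8 CPM (adjusted p = 0.0146, edgeR) and Car4, a capillary carbonic anhydrase gene, from 144.2 ± 4.63 to 234.0 ± 1.12 CPM (adjusted p = 0.0185), each the only called member of its list in edgeR and limma-voom. DESeq2 called 5 fibroblast and matrix genes (4 higher, 1 lower) and 2 endothelial markers (both higher). Adjusted over the list alone, 5 fibroblast and matrix genes rose and 1 fell, and 2 endothelial markers rose. As sets, fibroblast and matrix genes gave an adjusted p of 0.0682, endothelial markers 0.423, smooth muscle and pericyte markers 0.207 and mesothelial markers 0.18 (camera), the last with Msln at -1.02 ± 0.30 (-1.53 and passing without Kras_prtn3 replicate 1, -0.64 without Kras_prtn3 replicate 2, -0.62 without Kras replicate 1). The endothelial median was -0.01, its mean 0.06 and its test upward. Calls appeared for the endothelial list without Kras replicate 2 (adjusted p = 0.00667), the fibroblast list without Kras_prtn3 replicate 1 (0.00813), with DESeq2 (0.0313) and with library totals only (0.0442), and the mesothelial list without Kras replicate 2 (0.0287) or Kras_prtn3 replicate 1 (3.46e-06). Of 11 tested cardiomyocyte markers, 10 were below 0 (median -1.24), among them Actc1 at -1.12 ± 0.26 (passing without Kras_prtn3 replicate 1), none passed over all genes in edgeR (4 at an unadjusted p under 0.05, 1 called in DESeq2, 1 adjusted over the list alone), and the set was lower (camera, adjusted p = 3.71e-06; 0.674 with an estimated correlation). That call was lost without Kras_prtn3 replicate 2 (adjusted p = 0.168, mean -0.45), while without Kras_prtn3 replicate 1 the mean was -4.3 (adjusted p = 6.5e-40). The Kras_prtn3 libraries stand far apart here, as in Myh6, named after its values were seen, with 40.76 and 0.36 CPM against 18.18 and 16.35 in the Kras libraries. Skeletal muscle, adipocyte and erythroid markers gave adjusted p of 0.781, 0.591 and 0.973 (camera). The adipocyte list (median 0.06, test downward) was lower without Kras_prtn3 replicate 1 (adjusted p = 0.00383), and the erythroid list (median -0.12, mean 0.09) without Kras_prtn3 replicate 2 (0.000209).

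**Figure D3:**
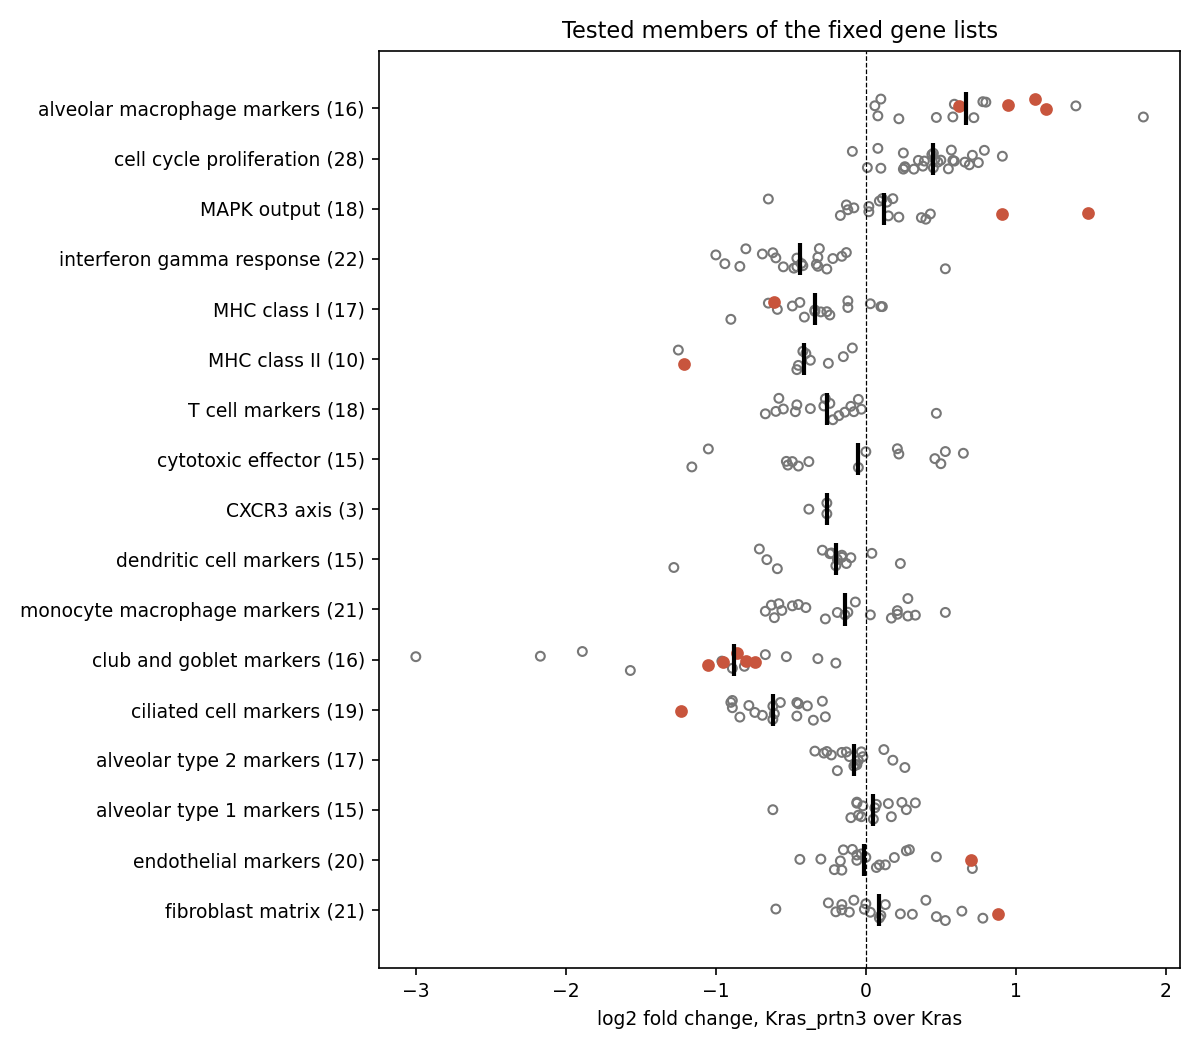
Log2 fold change (x axis, Kras_prtn3 over Kras) of each tested member of 17 gene lists fixed in advance, with the number of members in brackets. Filled points passed the edgeR test over all genes, open points did not, and bars mark list medians, which run from -0.88 for club and goblet markers to 0.67 for alveolar macrophage markers.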

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

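The newer quasi-likelihood form and the fit on autosomal genes were chosen after seeing the data. The number of changed genes was 35 (23 higher, 12 lower) without a low-count filter, 398 (209 and 189) with the robust fit, 459 (228 and 231) with DESeq2, 41 (19 and 22) with an absolute log2 fold change of at least 1 and 17 (10 and 7) at an adjusted p under 0.01. It was 117 with RLE factors and with a CPM minimum, 140 (104 higher, 36 lower) with library totals only, 124 with limma-voom, 108 with the newer quasi-likelihood form and 86 among autosomal genes. Leaving out a library gave 5 to 506 changed genes, 1 to 244 higher and 4 to 262 lower, and a lone sample was then assumed to vary like the other group. DESeq2 called 115 of the 117 genes in the same direction and the fit without a filter called 35 of them. None of the 117 changed sign in any alternative. The number of called lists was 13, and was 0 with an estimated correlation and 0 with the directional fry test, where 2 and 6 lists had an unadjusted p under 0.05. The mixed fry test called 11. Among them were lists that camera did not call, such as hypoxia and glycolysis (adjusted p = 0.00565), smooth muscle and pericyte (0.0168), fibroblast and matrix (0.0236) and mature neutrophil genes (0.0358). The replicate numbers are not stated to pair samples, and deviations of same-numbered samples correlated at 0.14. With a replicate block, which leaves a single residual degree of freedom, 1585 genes were called (742 higher, 843 lower). They held 30 of the 54 genes named here that passed the low-count filter and are not among the 117, such as Cxcl9, Stat1, Marco, Ccl5 and the clock genes Nr1d1, Nr1d2, Npas2, Cry1 and Arntl. Set calls that differed under the block were those of T cell (adjusted p = 0.0932), mature neutrophil (0.0427) and mesothelial markers (0.0148).

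The Prtn3 ratio stayed within its counting interval in each alternative (0.382 to 1.26 when a library was left out). Directions turned only for results that had not passed. For lists the direction is that of the set test, which can differ from the sign of the mean. It turned with the replicate block for type I interferon (mean log2 fold change 0.02), progression (-0.01) and clock genes (0.10), among autosomal genes for type I interferon (0.01) and erythroid genes (0.15), with DESeq2 for erythroid (0.09) and clock genes (0.19), and with fry for type I interferon genes (0.01). Myh6 (0.25 in the main fit) stood at -0.62 with the replicate block and -2.11 with limma-voom. With library totals only, Trp53 stood at 0.03 and Cd8a at 0.00. When a library was left out, it turned in at least 1 fit for 12 lists, whose means ran from -0.72 to 0.02 for the CXCR3 axis, -0.09 to 0.14 for type I interferon, -0.26 to 0.12 for B and plasma cell, -0.10 to 0.14 for alveolar type 1, -0.04 to 0.22 for endothelial, -1.48 to -0.03 for mesothelial, -0.29 to 0.30 for skeletal muscle, -3 to 1.6 for adipocyte, -1.24 to 0.44 for erythroid, -0.21 to 0.15 for progression, -0.25 to 0.40 for stress and -0.14 to 0.26 for clock genes. Single genes that turned ran from -0.87 to 0.18 (Cxcl10), -0.65 to 0.05 (Cxcr3), -0.16 to 0.13 (Trp53), -0.25 to 0.12 (Cd8a), -0.25 to 0.56 (Ear1), -0.02 to 0.16 (Ear2), -0.78 to 0.10 (Hdc), -0.25 to 0.04 (Oasl2), -0.19 to 0.07 (Ager) and -5.57 to 1.24 (Myh6, passing at both ends, without Kras_prtn3 replicate 1 and without replicate 2). The cause of these changes was not tested.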

Other observations

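The tests of sex, of cell and tissue shares, of an equal rise of macrophage genes, of an MHC haplotype, of a single library and of the time of day were chosen only after the result was seen. Genes of the circadian clock moved in opposite directions. Per1, a gene of the negative arm, rose from 44.7 ± 5.23 to 125.3 ± 39.4 CPM (SD, n = 2), and Per2, of the same arm, fell by 1.07 on the log2 scale (edgeR, adjusted p = 0.0272 and 0.0399). The other 15 clock genes did not pass over all genes in edgeR, while Cry1 passed in limma-voom and Arntl in DESeq2. Of these 15, Nr1d1 and Nr1d2 (1.92 ± 0.41) rose and Cry1, Arntl and Npas2 fell adjusted over the list alone. Nr1d1, which encodes a repressor of Arntl, had 24.3 and 19.83 CPM in the Kras libraries and 204.35 and 36.58 in the Kras_prtn3 libraries, and Npas2 had 52.74 and 52.7 against 10.45 and 34.29. Cry1 stood at -1.55 ± 0.28 and Arntl at -0.82 ± 0.23, with adjusted p of 0.0542 and 0.111 (edgeR). These 5 were named after their values were seen. Without Kras_prtn3 replicate 1, Nr1d1 stood at 0.73, Nr1d2 at 1.02, Npas2 at -0.62 and Arntl at -0.47. Without Kras_prtn3 replicate 2, Npas2 stood at -2.33 and Arntl at -1.3. As a set the clock list did not shift in one direction (camera, adjusted p = 0.99, median 0.11, mean 0.19, test downward). Such a test misses changes in opposite directions, and the mixed fry test gave an adjusted p of 0.0611. Without Kras_prtn3 replicate 2 the camera direction was upward, with a mean of 0.26.

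Single called genes outside the lists are given as examples only. Lilrb4a, an inhibitory receptor gene next in kind to Lilr4b, stood at 1.03 ± 0.09 (adjusted p = 0.00551, edgeR), and Clec7a, the gene of the fungal glucan receptor dectin-1, at 0.90 ± 0.09 (adjusted p = 0.00941). H2-Q9, an MHC class I gene outside the lists, fell by 1.21 (adjusted p = 0.00551). All 3 were named after their values were seen, and none passed when either Kras library was left out.

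The changed genes as a whole run along the Y-linked difference. Genes on X and Y made up 12.8% of the 117 calls (exact 95% interval 7.4 to 20.3), which does not show whether sex-linked genes act on the others. There were 0 pairs of libraries across the groups alike in Y-linked expression, so an effect of sex on autosomal genes and an effect of the Prtn3 label cannot be told apart. A chromosome segment around Prtn3 from another strain stays open. It was not supported, as 1.71% of the calls (2 genes, Vpreb3 and Derl3) lay within 10 Mb, where 1.64% of the tested genes lie (Fisher's exact test, two-sided p = 0.718), but the upper limit of that share, 6.0%, lies above the 5% bound set beforehand, and position does not show effects on genes elsewhere. For the clock genes, the mean absolute log2 fold change of 0.85 lay above all 10000 expression-matched random lists (highest 0.68). The random lists were matched on expression and not on the spread within a group, and the Kras_prtn3 libraries stood far apart in clock genes such as Nr1d1. The comparison therefore does not separate a difference between groups from one between libraries, and does not show its cause. The mixed fry test of the clock list did not pass (adjusted p = 0.0611). Another time of day at collection is therefore not singled out and stays open.

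Alveolar macrophage markers were higher and airway markers lower in Kras_prtn3. A lower share of the main epithelial type would raise other cell types alike, so it does not account for the lower airway markers (ciliated median -0.62). Those markers define the pattern, so this is no separate test. The alveolar type 2 markers had a median of -0.08, and whether such a share adds to the macrophage rise was not tested. A larger share of alveolar macrophages may contribute, as the more abundant members had a median of 0.42 and 16 of 16 were above 0, and the heterogeneity of 10.8 per degree of freedom between their values does not decide on cell number, since transcripts of these genes in other cells were not measured. A smaller share of airway tissue in the pieces sampled may account for the club and goblet median of -0.88. How the pieces were taken, sex and the Prtn3 label stay open.

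MHC and interferon-gamma response genes were lower in Kras_prtn3. All 22 response genes lie outside chromosome 17 (median -0.44, 21 of 22 below 0), so position alone does not tie them to another MHC haplotype. That is the list value already given and no separate test. A haplotype stays open for both MHC lists, most of whose genes lie on chromosome 17, and for H2-Q9. The direction did not rest on a single Kras_prtn3 library, while the size differed between them. The median of the MHC and response genes together was -0.47 without Kras_prtn3 replicate 1 and -0.27 without Kras_prtn3 replicate 2. The bound for this comparison was set after some values per library had been seen, so it is no separate test. Sex, cell makeup and the Prtn3 label stay open.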
